A study of Caenorhabditis elegans with 6 samples.

How the data were processed

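The series holds 6 labelled libraries of C. elegans L1 larvae, 3 from sorted RIS neurons and 3 from whole animals, grouped by their titles. Per the labels' protocols, larvae were synchronized with hypochlorite and hatched overnight in M9 buffer. RIS cells carrying mKate under the flp-11 promoter were sorted by flow cytometry from dissociated larvae into Trizol, and cDNA was made with a low-input SMART-Seq kit before sequencing on an Illumina HiSeq instrument. The reference larvae were N2 animals frozen over liquid nitrogen. The sorting notes name AVK and mCherry where the other labels name RIS and mKate, and the libraries are called RIS here after their titles and cell type. The aligner, the counting tool, the genome build and the annotation are not given in the sources used here.

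The values analysed were those of a single table with 12072 genes and 12 columns, deposited by the authors. Per the file headers it holds a log2 fold change, a mean log2 CPM, an F score, a p-value and a false discovery rate for each gene, the format that the authors' edgeR quasi-likelihood test writes. The log2 fold change deposited by the authors is positive for genes higher in RIS, which the file name and the sign of flp-11 both give. The F score deposited by the authors has 1 numerator degree of freedom. The p-value deposited by the authors is unadjusted, and its Benjamini-Hochberg adjustment was recomputed with a largest difference of 3.44e-15 from the deposited false discovery rate. Library totals, normalization factors, filters and the prior count of the fit are unknown, so the depth of each library and the precision it gives are unknown as well. Mean CPM was computed as 2 to the power of the deposited log2 CPM, which averages over both groups. The table has no values per library, and 0 such columns were left unused.

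Because the table has no counts, the branch of the design fixed for a deposited comparison was used. Genes were called at the authors' adjusted p below 0.05. For each of 34 gene lists, 24 fixed by gene names and 10 by name prefix, members called in each direction were counted over all genes and with Benjamini-Hochberg adjustment over the list alone. The list median was placed among the medians of 10000 random lists of the same size drawn from the same 10 bins of mean expression, with a fixed seed. This percentile describes these libraries and is not a p-value. The lists, the alternatives and the rule for named genes were fixed before the data were examined. The rule named every member of the RIS, GABA, AVK and ALA lists, the 10 largest rises and falls among called genes with public names at or above median expression, and up to 4 members of each other list by adjusted p (6 in the flp, nlp, peptide receptor and ceh families). Up to 2 further members called against the direction of their list were added. Listed members absent from the table were not analysed here. Genes named outside the rule, chosen after their values were seen, are cho-1, cha-1, unc-54, act-5, pat-10, fos-1, jun-1, hsp-4, hsp-16.2, hsp-16.41, F44E5.4, F44E5.5, F46C5.7, F46C5.4, C10C6.7 and ZK1307.7, and those of the closing paragraphs on gene families and mitochondrial genes.

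The denominator degrees of freedom were recovered for each gene from F and p. They were 6.76 for 11902 genes and 5.76 for 170, a loss that arises when all libraries of a group have no reads. A standard error was approximated as the absolute log2 fold change over the square root of F, and used only for approximate 95% intervals and for a test relative to the median of all genes. Genes with few RIS reads lie on discrete positions of the sum of log2 fold change and log2 CPM. In a model with 2 RIS libraries of unequal size, 3 reads reached positions up to 4.74 above the genes without reads (log2). The 943 genes up to a small margin above that position, all of them lower in RIS by more than a set limit, are called genes at few RIS reads. Those without reads are included. Of the 943, 935 were called lower, 29.4% of the falls. Positions of 3 and more reads overlap, so some of these genes can have more than 3. Their fitted fold changes depend on the unknown prior count, so none are printed, and list medians and counts that include them are fitted values. The positions were compared with a negative binomial model of 2 or 3 libraries. Of the gene identifiers, 12052 were found in the Ensembl release 115 annotation of WBcel235, all on the same chromosome, and 68.6% of them shared a start or end. The table names no build, so coordinates are printed as the table lists them.

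Alternatives were an adjusted p below 0.01, a fold change of at least 2, genes at or above median expression, recomputed adjustment, public gene names only and unmatched random lists. Added after the table was seen were fold changes relative to the median of all genes and the removal of genes without RIS reads. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The test relative to the median was tested on simulated values for this comparison, with the errors of the 12072 genes and 200 changed genes. It recovered 24.5% of genes changed by a log2 fold of 4, with 3.92% of the calls false, and 0% at a log2 fold of 2. In the data 4446 genes were called by this test, far more than were changed here, so these recoveries do not carry over. The simulated errors followed the form that the test assumes, so the share of false calls is no independent check. Of 100 simulated unchanged lists 6% lay outside the central 95% of random lists, and of 100 lists shifted by a log2 fold of 2, 80% lay above the 97.5th percentile. The unchanged lists were themselves random draws, so a small share outside was built in and does not cover lists of related genes. Each simulated list had 20 genes, so the 80% does not carry over to shorter lists. For the read positions, simulated with 467 genes, an added library raised the log-likelihood by 0.00627 when 2 libraries were simulated and by 141 when 3 of different sizes were.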

Results

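RNA was sequenced from RIS neurons sorted out of dissociated L1 larvae of Caenorhabditis elegans and from whole L1 larvae of the N2 laboratory strain, which served as the reference. RIS is an interneuron that uses GABA and neuropeptides, and its activity brings on sleep-like quiescence. The labels list 3 RIS libraries and 3 reference libraries, and the comparison asks which transcripts the sorted neurons hold at other levels than the whole animal. The only values analysed here were those of the authors' deposited table of that comparison, so levels, depth and spread per library are unknown. No label says that the libraries came from separate cultures. The p-values therefore measure only the spread between these libraries, which may be technical.

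Among the 34 gene lists fixed in advance, those of stress genes, RIS markers and neuropeptide processing had some of the highest median fold changes. The lists of ciliated sensory neurons, pharynx and collagens had the lowest. Of 12072 genes, 4371 (36.2%) differed at an adjusted p below 0.05 in the authors' deposited table, 1188 higher and 3183 lower in RIS. The called rises had a median log2 fold change of 2.90 and the called falls one of −5.06. At least a 32-fold change was listed for 165 of the rises and 1623 of the falls. Without the 943 genes at few RIS reads, near or below the positions that 3 RIS reads reached, 2248 falls remained, with a median of −4.10 and 736 of at least 32-fold. The median log2 fold change of all genes was −0.78, so the zero of the table lies above the typical gene. Relative to that median, 45.0% of the calls were higher in RIS, against 27.2% as deposited. The fold changes below are as deposited. No fold is given for genes at few RIS reads, since theirs depends on an unstated prior count. Folds of genes just above those positions are printed but are uncertain as well.

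**Figure D1:**
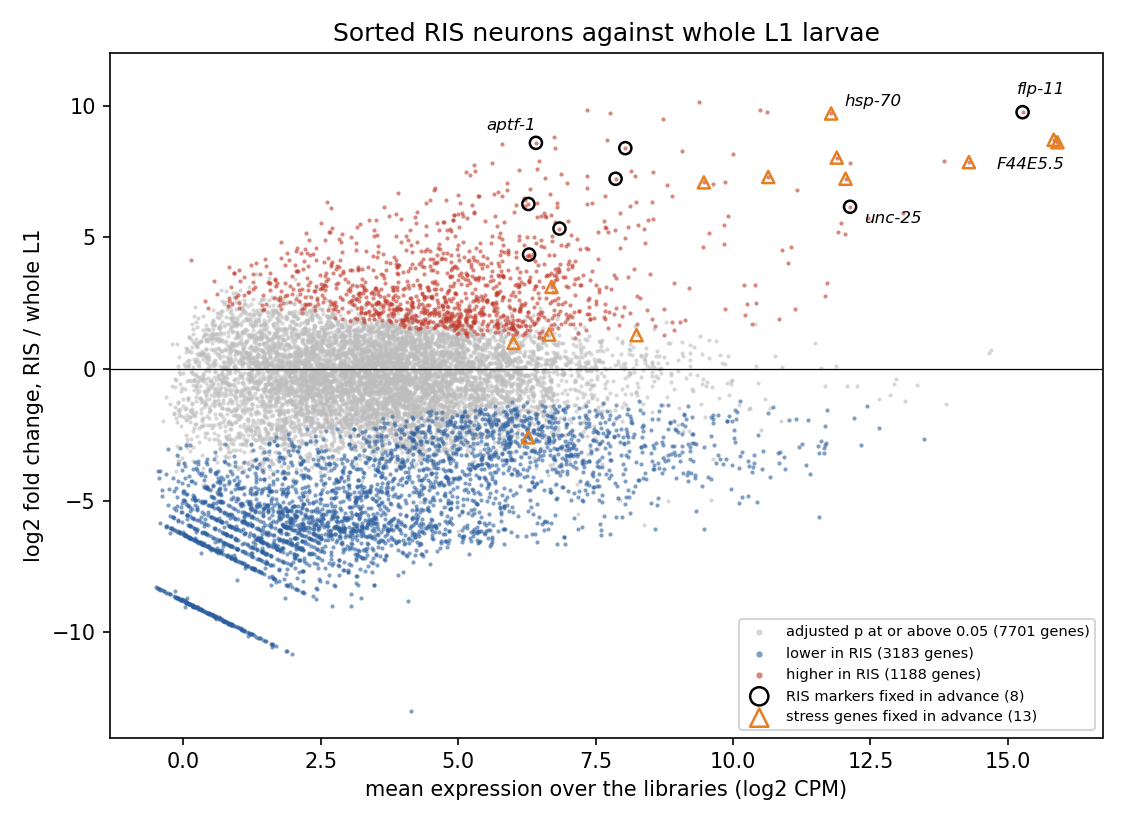
Log2 fold change (RIS over whole L1, vertical axis) against mean expression over the libraries (log2 CPM, horizontal axis) for 12072 genes of the authors' deposited table, with 1188 genes higher in red, 3183 lower in blue and the rest in grey. Open circles are 8 RIS markers and open triangles 13 stress genes, and the parallel bands at the lower left are genes with few or no RIS reads, whose fitted fold changes rest on those few reads.

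Genes that mark RIS were enriched together. The sleep-inducing neuropeptide gene flp-11 rose 862-fold (log2 fold change 9.75, approximate 95% interval 8.54 to 10.96, adjusted p = 0.000798) in the authors' deposited table, at a mean of 39456 CPM. The AP2 transcription factor gene aptf-1, which RIS needs for flp-11 expression, rose by a log2 fold change of 8.59 (interval 7.45 to 9.72, adjusted p = 0.000798) in the authors' deposited table. For the serotonin receptor gene ser-4 the authors' deposited table gave 8.39 and for the LIM homeobox gene lim-6 it gave 7.22. All 8 measured markers of the RIS list were higher, also when adjusted over the list alone, with a median of 6.74 at percentile 100 of 10000 random lists matched on expression; srx-9 was not analysed here. The sort used the flp-11 promoter, so the rise of flp-11 was selected for by the design. In the coordinates of the authors' deposited table, for which no build is named, flp-11 (WBGene00001454) spans X 4677342 to 4678129 and aptf-1 (WBGene00019424) spans II 6454974 to 6456440.

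GABA genes rose with the RIS markers, 3 of which they share. For unc-25, the glutamate decarboxylase gene, the authors' deposited table gave a log2 fold change of 6.16 (71.5-fold, interval 5.01 to 7.31, adjusted p = 0.00143). It was 6.27 for the vesicular transporter gene unc-47 and 5.33 for its partner unc-46 in the authors' deposited table. The plasma membrane GABA transporter gene snf-11 was not called there (−1.83, adjusted p = 0.259). Thus 3 of 4 members were higher over all genes and adjusted over the list alone, and the list median of 5.75 lay at percentile 99.99. Pathways of other transmitters had no member higher, at either the adjusted or the unadjusted threshold of 0.05. Of 10 measured members 4 fell (5 adjusted over the list alone), all of them monoamine genes. These were the dopamine genes dat-1 (−5.20) and cat-2 (at few RIS reads), the decarboxylase gene bas-1 (−2.92) and the vesicular transporter gene cat-1 (−4.11) in the authors' deposited table. Their list median of −2.67 lay at percentile 9.62, and relative to the median of all genes the calls on bas-1 and cat-1 ended. The acetylcholine genes unc-17 (1.27), cho-1 (1.58) and cha-1 (−0.47) were not called in the authors' deposited table.

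The labels name another neuron, AVK, in their sorting notes, with mCherry in place of the mKate of the strain, although cell type, source and titles name RIS. None of the 4 AVK genes fixed in advance passed the adjusted threshold of the authors' edgeR-format test, over all genes or adjusted over the list alone. At an unadjusted p below 0.05 there was 1, twk-47, which lay lower (−2.42, adjusted p = 0.0750) in the authors' deposited table. The peptide gene flp-1, the usual marker of AVK, had a log2 fold change of 0.66 (approximate 95% interval −0.42 to 1.73, adjusted p = 0.305) in the authors' deposited table. Its neighbours in the list were unc-42 at 1.27 (adjusted p = 0.163) and fax-1 at 0.70 (adjusted p = 0.735) in the authors' deposited table. The list median of 0.68 lay at percentile 91.9. Relative to the median of all genes, flp-1 (1.44, adjusted p = 0.0452) and unc-42 (2.05, adjusted p = 0.0415) were called higher. Both lay far below the RIS markers, of which all 8 measured were higher as deposited, with a list median of 6.74.

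The machinery that makes neuropeptides rose strongly. The authors' deposited table gave log2 fold changes of 6.80 for the proprotein convertase gene egl-3, 5.92 for the amidating lyase gene pgal-1, 5.82 for the dense core vesicle gene ida-1 and 5.72 for the convertase chaperone gene sbt-1, with adjusted p from 0.00134 to 0.00143. Of 10 such genes 8 were higher and 0 lower, over all genes and adjusted over the list alone, with a median of 5.38 at percentile 100.

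Peptide genes themselves split. Beside flp-11, the FMRFamide-like peptide genes flp-26 (5.67), flp-34 (4.61) and flp-27 (3.58) rose and flp-13 (−4.72) and flp-2 (−2.56) fell in the authors' deposited table. Of 28 flp genes 5 were higher and 3 lower, the same counts as adjusted over the list alone. Relative to the median of all genes 8 were higher and 1 lower, and flp-2 lost its call. Among 39 nlp genes 4 were higher and 5 lower, as when adjusted over the list alone, and 9 and 3 relative to the median of all genes. In the authors' deposited table nlp-11 (7.52), nlp-13 (7.47), nlp-8 (7.34) and nlp-35 (4.43) rose, whereas nlp-33 (−4.43) and nlp-26 (−4.32) fell. The medians of 0.36 for flp and 0.23 for nlp genes lay at percentiles 98.8 and 99.5. Of 19 insulin-like genes 3 were higher and 1 lower, the same adjusted over the list alone, with ins-27 (3.33), ins-29 (2.32) and ins-24 (2.18) higher in the authors' deposited table. The lower member was ins-5, which by its degrees of freedom had no RIS reads, so no fold is given. The insulin-like median of −0.85 lay at percentile 61.7.

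Genes used across the nervous system were enriched as well. The authors' deposited table gave 4.59 for synaptobrevin (snb-1), 4.09 for the axonal kinesin gene unc-104, 3.77 for synaptotagmin (snt-1) and 3.67 for the vesicle priming gene unc-13, at adjusted p between 0.00205 and 0.00428. Of 22 panneuronal genes 17 were higher (18 adjusted over the list alone) and 0 lower, and 18 were higher at an unadjusted p below 0.05. Their median of 2.61 lay at percentile 100.

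The lists of biogenic amine receptors and peptide receptors were among the most enriched. The biogenic amine list was drawn up to include muscarinic receptor genes (gar), which are not monoamine receptors. Of its 20 measured genes 13 were higher and 1 lower, also adjusted over the list alone, with a median of 3.70 at percentile 100. After ser-4, the authors' deposited table gave 6.57 for the ligand-gated channel gene lgc-53, 5.66 for the dopamine receptor gene dop-1 and 4.57 for dop-5, and the muscarinic receptor gene gar-3 fell (−5.74). Of 50 peptide receptor genes 23 were higher and 8 lower (25 and 9 adjusted over the list alone), with a median of 2.28 at percentile 100. The cholecystokinin-like receptor gene ckr-1 (8.69) led the authors' deposited table among them, before npr-32 (7.53), dmsr-2 (6.80), frpr-7 (6.31), dmsr-6 (6.24) and npr-29 (5.80). The falls with the smallest adjusted p, frpr-15 and npr-35, lay at few RIS reads. GABA and glutamate receptor genes went both ways, with 6 of 24 higher and 5 lower, as when adjusted over the list alone. There the authors' deposited table gave 5.21 for the metabotropic receptor gene mgl-2 and 4.08 for the glutamate-gated chloride channel gene avr-15, and nmr-1 and glr-8 fell to few RIS reads. Their median of −0.22 (percentile 88.6) is above 0 relative to the median of all genes, where 8 were higher and 5 lower.

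Ion channel genes went both ways. Of 19 genes of voltage-gated and calcium-activated channels 8 were higher and 3 lower (9 and 3 adjusted over the list alone; 12 and 2 relative to the median of all genes), with a median of 2.02 at percentile 100. The authors' deposited table gave 6.56 for the potassium channel gene exp-2, 3.74 for the calcium channel gene unc-2, and 3.47 and 3.38 for unc-79 and unc-80, which serve the sodium leak channel. The potassium channel genes kqt-3 (−4.20) and egl-36, the latter at few RIS reads, fell in the authors' deposited table. Of 31 twk potassium channel genes 3 were higher and 6 lower, also adjusted over the list alone, and the median of −1.35 lay at percentile 17.3. The genes twk-17 (2.41) and twk-29 (2.09) rose while twk-34 (−5.85), twk-28 (−5.69), twk-14 (−5.66) and, at few RIS reads, twk-10 fell in the authors' deposited table. Of 20 gap junction innexin genes 2 were higher, unc-9 (3.66) and inx-1 (3.27), and 9 lower, inx-3 (−6.20) and inx-6 (−5.66) among them, in the authors' deposited table. Adjusted over the list alone, 3 innexins were higher and 9 lower, and relative to the median of all genes 5 and 5. The innexin median of −1.44 lay at percentile 17.7.

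The EGF receptor pathway, through which RIS and the ALA neuron are driven in stress-induced sleep, had more members higher than lower. The receptor gene let-23 rose by a log2 fold change of 4.34 (adjusted p = 0.00300) in the authors' deposited table. The adaptor gene sem-5 (4.10), the phospholipase gene plc-3 (3.38) and the Ras gene let-60 (2.85) rose as well, whereas the ligand gene lin-3 (−4.73) and the IP3 receptor gene itr-1 (−2.75) fell in the authors' deposited table. Of 13 measured members 5 were higher and 2 lower (5 and 3 adjusted over the list alone), with a median of 1.23 at percentile 99.6. Markers of ALA diverged. The peptide gene nlp-8 rose (7.34) and ver-3 (−5.17) and flp-13 (−4.72) fell, while ceh-10 (−1.13) and flp-24 (−0.79) were not called in the authors' deposited table. So 1 of 5 measured ALA genes was higher and 2 were lower, also adjusted over the list alone, and their median of −1.13 lay at percentile 50.7.

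Markers of other neuron classes were mostly lower or uncalled. Of 11 measured genes of ciliated sensory neurons 7 fell and 1 rose, also adjusted over the list alone, with a median of −4.68 at percentile 0.605. The intraflagellar transport genes dyf-1 (−5.72), osm-5 (−5.44) and che-3 (−4.68) fell in the authors' deposited table, bbs-1 fell to few RIS reads, and the transcription factor gene daf-19 rose (1.49, adjusted p = 0.0343). Among 7 touch receptor neuron genes mec-18 (−3.43), mec-4 (−2.79) and mec-17 (−1.23) fell and the alpha-tubulin gene mec-12 rose (3.21) in the authors' deposited table. These 3 lower and 1 higher were the same adjusted over the list alone, with a median of −1.23 at percentile 32.8, and relative to the median of all genes 1 stayed lower. Of 7 cholinergic motor neuron genes the receptor gene acr-2 rose (4.21) and the transcription factor gene unc-3 fell (−4.36), and unc-129 (−1.82) was not called in the authors' deposited table. The median of that list was −0.42 (percentile 57.6), above 0 relative to the median of all genes. Of 4 genes of the D-type GABA motor neurons alr-1 rose (4.56) and flp-13 fell, and unc-30 (−0.44) and ttr-39 (−1.11) were not called in the authors' deposited table. Their median of −0.78 lay at percentile 47.4. The counts of both motor neuron lists were the same adjusted over the list alone.

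Markers of other tissues fell to different degrees. Pharyngeal genes fell furthest, with 10 of 12 lower and 1 higher, also adjusted over the list alone, and a median of −4.29 at percentile 0.03. In the authors' deposited table phat-2 (−6.32), the pharyngeal myosin genes myo-2 (−5.13) and myo-1 (−3.93) and the troponin gene tnc-2 (−2.59) fell, and the organ identity gene pha-4 rose (3.02, adjusted p = 0.0110). Of 14 hypodermal and cuticle genes 9 were lower (10 adjusted over the list alone) and 0 higher, with a median of −2.57 at percentile 1.05, or 3.04 among random lists not matched on expression. They included wrt-2 (−6.06), elt-3 (−5.69), dpy-13 (−4.12) and sqt-3 (−3.89) in the authors' deposited table. Of 106 collagen genes 71 were lower (77 adjusted over the list alone) and 1 higher, col-83 (3.03), in the authors' deposited table. Among the lower ones were col-131 (−7.41), col-41 (−5.40), col-65 (−4.91) and col-43 (−4.27) in the authors' deposited table, and the collagen median of −2.98 lay below all random lists.

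Muscle and intestinal markers lay closer to the typical gene. Of 15 body wall muscle genes 8 were lower (9 adjusted over the list alone) and 0 higher, with a median of −1.61 at percentile 23.9. In the authors' deposited table paramyosin (unc-15, −2.99), the myosin gene myo-3 (−2.81) and the twitchin gene unc-22 (−2.74) fell, and the myogenic factor gene hlh-1 fell to few RIS reads. Of 12 measured intestinal genes 7 were lower and 0 higher, also adjusted over the list alone, and the median of −1.89 lay at percentile 12.1. The peptide transporter gene pept-1 (−5.62), the protease gene cpr-6 (−3.78), pho-1 (−3.28) and ifc-2 (−2.59) fell in the authors' deposited table. Relative to the median of all genes 4 muscle, 3 intestinal and 5 hypodermal genes stayed lower and 1 muscle gene, unc-54, was higher.

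The remaining tissue lists were those of glia, germline and coelomocytes. In the authors' deposited table the glial gene che-14 fell (−6.26) and pros-1 (−1.70) was not called. With daf-6 and mls-2, which fell to few RIS reads, 3 of 9 measured glial genes were lower, also adjusted over the list alone. The glial median of −0.67 (percentile 55.6; mean −2.44) is above 0 relative to the median of all genes. None of 9 measured germline genes passed the adjusted threshold, over all genes or adjusted over the list alone, and 1 lay lower at an unadjusted p below 0.05. The germline helicase genes glh-1 (−1.58), glh-2 (−3.06) and glh-4 (1.30) and the meiotic gene him-3 (1.13) were not called in the authors' deposited table. The germline median was 0.84 (percentile 98.1, or 97.1 among random lists not matched on expression) and the mean −0.24. The coelomocyte gene unc-122 rose (2.63, adjusted p = 0.0391), while lgc-26 (1.89) and cup-4 (−0.23) were not called in the authors' deposited table. That is 1 of 3, also adjusted over the list alone, with a median of 1.89 at percentile 94.2. Relative to the median of all genes 2 of the 3 were higher.

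**Figure D2:**
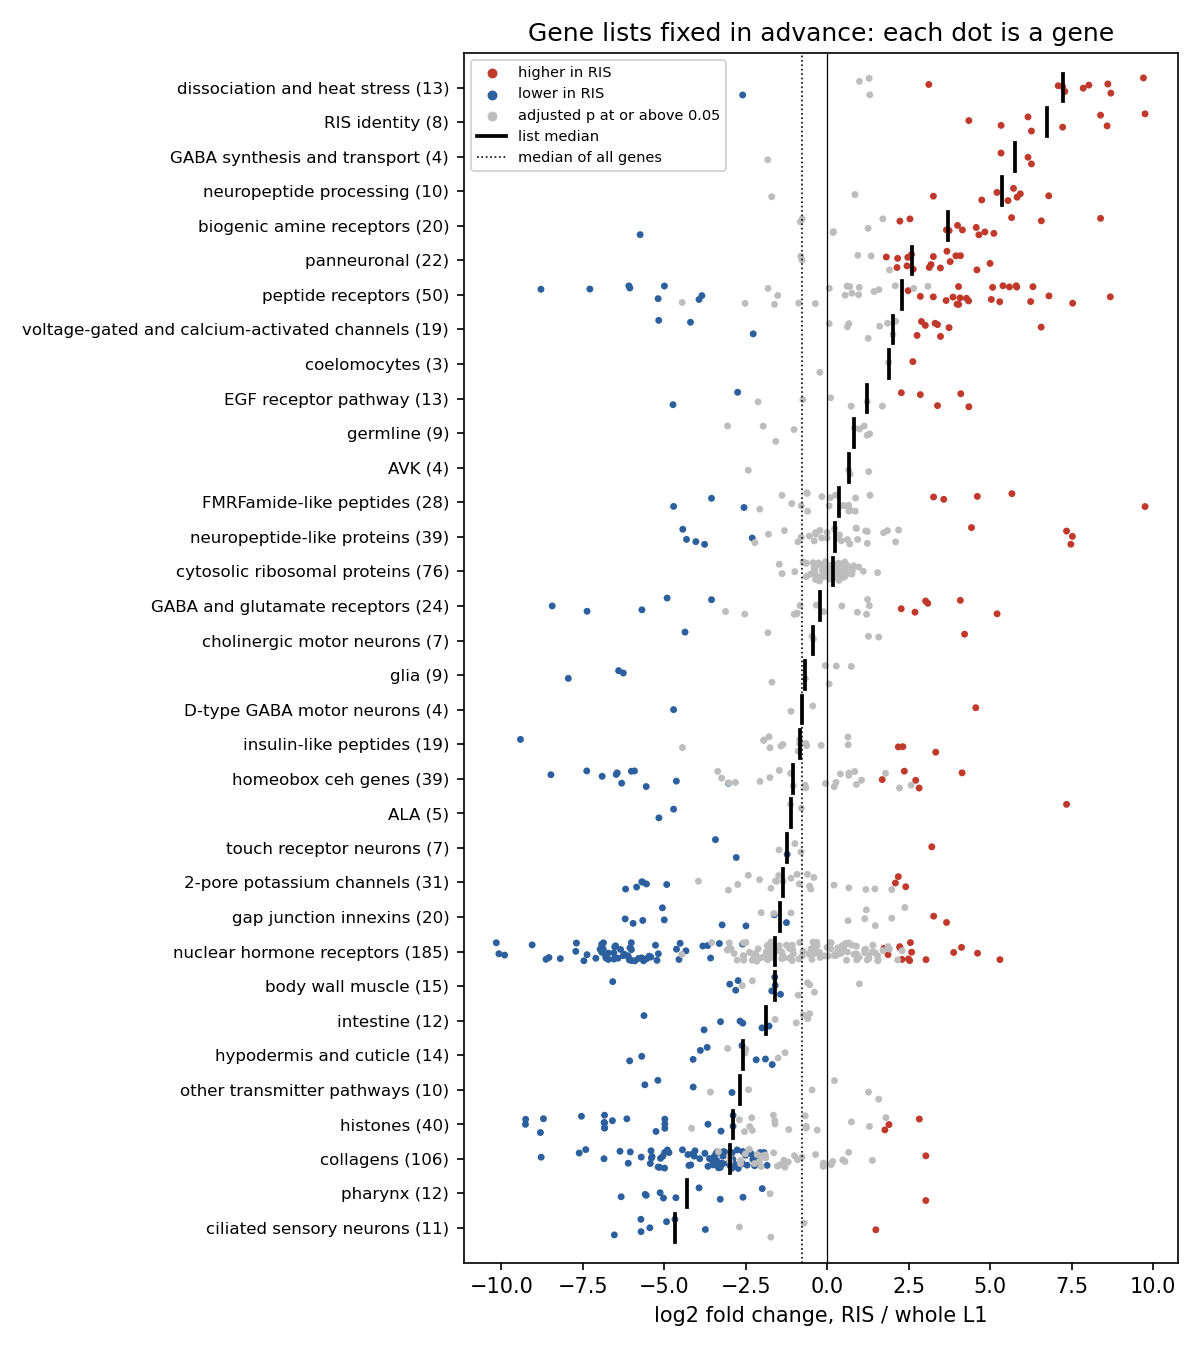
Log2 fold change (RIS over whole L1, horizontal axis) of every measured member of the 34 gene lists fixed in advance, from the authors' deposited table, sorted by list median, with the number of members in brackets, red for higher, blue for lower and grey for uncalled genes. Thick black bars are list medians, from 7.23 for the stress list to −4.68 for the ciliated neuron list, and the dotted line is the median of all genes, −0.78; the points furthest left are genes with few or no RIS reads.

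Inducible heat shock genes formed the other group of large rises. The authors' deposited table gave log2 fold changes of 9.70 for hsp-70 (approximate 95% interval 8.10 to 11.30, adjusted p = 0.00125), 8.70 for F44E5.4 and 8.61 for F44E5.5, all of the HSP70 family. For the small heat shock genes hsp-16.1, hsp-16.48, hsp-16.11, hsp-16.41 and hsp-16.2 the authors' deposited table gave 8.03, 7.85, 7.29, 7.23 and 7.09. These 8 genes took 15.3% of the mean CPM, and F44E5.5 and F44E5.4 had the highest of them at 61219 and 58430 CPM. Mean CPM averages over both groups, so their share of the RIS reads was higher than 15.3%, by an amount that is unknown without values per library. The oxidative stress gene gst-4 fell (−2.60), and hsp-4 of the endoplasmic reticulum (1.31, adjusted p = 0.0580), jun-1 (1.28) and fos-1 (0.99) were not called in the authors' deposited table. Of 13 measured stress genes 9 were higher and 1 lower (11 and 1 adjusted over the list alone; 11 and 0 relative to the median of all genes, where gst-4 was not called and hsp-4 and jun-1 were higher), and the median of 7.23 lay at percentile 100. Several of these genes are near-identical neighbours, such as F44E5.4 (II 11757106 to 11759323) and F44E5.5 (II 11759640 to 11761853), so the split of reads within a pair is uncertain. The RIS cells were dissociated and sorted and the reference larvae were frozen whole, so handling differed with the group. Strain differed with it too, since the RIS cells came from a strain with the mKate reporter and the reference was N2.

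Most genes of the homeobox and nuclear hormone receptor families were not called, and lower calls outnumbered higher ones, as over all genes, of which 26.4% were lower. Of 39 ceh homeobox genes 11 were lower (12 adjusted over the list alone), 5 higher and 23 not called, with a median of −1.04 at percentile 40.1. Relative to the median of all genes 10 ceh genes were lower and 8 higher. In the authors' deposited table ceh-62 (4.14) and ceh-44 (1.69) rose and ceh-92 (−6.48) fell, while ceh-33, ceh-79, ceh-23 and ceh-57 fell to few RIS reads. Of 185 nuclear hormone receptor genes 114 were not called, 57 were lower and 14 higher (57 and 15 adjusted over the list alone; 53 and 24 relative to the median of all genes), with a median of −1.60 at percentile 0.07. The authors' deposited table gave −7.10 for nhr-176, −6.87 for nhr-238 and −6.79 for nhr-62, with nhr-212 at few RIS reads, against 4.12 for nhr-71 and 3.88 for nhr-17.

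Many histone genes fell, and no ribosomal protein gene passed the threshold. Of 40 histone genes 20 were lower (22 adjusted over the list alone) and 3 higher (4 adjusted over the list alone), with a median of −2.89 at percentile 1.46. Relative to the median of all genes 12 histone genes were lower and 5 higher. The authors' deposited table listed identical values for his-19, his-21, his-51 and his-53, which lay at few RIS reads, and rises for his-35 (2.83) and his-41 (1.89). Histone genes are near-identical copies, and 16 of the 40 lay at few RIS reads. Of 76 cytosolic ribosomal protein genes 0 passed the adjusted threshold of the authors' edgeR-format test, over all genes or adjusted over the list alone, and 1 was higher at an unadjusted p below 0.05. The authors' deposited table gave 1.55 for rpl-38 (adjusted p = 0.0652), 1.11 for rpl-35, −1.39 for rps-7 and −1.47 for rpl-19. Their median of 0.19 lay at percentile 99.7, and 4 were called higher relative to the median of all genes.

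Among genes with public names at or above the median expression of 11.9 CPM, the rises outside the lists above were led by the chemoreceptor-family genes srg-69 (9.83) and srx-2 (9.72) in the authors' deposited table. The tachykinin receptor gene tkr-1 (8.40) and the calcineurin regulator gene rcan-1 (8.16) followed in the authors' deposited table, with adjusted p of 0.000798 and 0.00108. In the other direction the authors' deposited table gave −7.84 for mam-2, −7.72 for the cytochrome P450 gene cyp-35A5 and −7.34 for osm-8, and placed the ether lipid monooxygenase gene agmo-1 at few RIS reads. Further falls were oac-32 (−7.21, adjusted p = 0.0352), the Argonaute gene sago-2 (−7.08), the lectin gene clec-26 (−7.06) and the sodium-proton exchanger gene nhx-1 (−7.05) in the authors' deposited table. Chosen after their values were seen, the neighbours F46C5.7 (10.12) and F46C5.4 (9.84) lay above srg-69, and C10C6.7 (9.77) and ZK1307.7 (9.49) just below it, in the authors' deposited table.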

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

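Centring on the median and the removal of genes without RIS reads were chosen after the data were seen. No called gene among the 188 named ones changed direction under these alternatives or the planned ones that could be run. That outcome was fixed in advance and is no sign of robustness. All called genes were changed at least 2-fold, which is more than the log2 shift of 0.78 from centring. The other alternatives leave the fold changes as they are. A stricter threshold or fewer genes lowered counts by construction. At an adjusted p below 0.01, 2307 genes were called, 591 higher and 1716 lower. Among genes at or above median expression 2405 were called, 1468 of them lower. With public gene names only, 2423 were called, 768 higher and 1655 lower. Relative to the median of all genes 1999 were higher, because the shift of 0.78 adds to each fold change. A 2-fold minimum, recomputed adjustment and removal of genes without RIS reads moved no count by over 1.5 times. Among unmatched random lists the germline list (percentile 97.1 against 98.1) and the hypodermal list (3.04 against 1.05) no longer lay outside the central 95%.

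At the stricter threshold 27 named genes lost their call. Relative to the median, 9 lost it (bas-1, cat-1, mec-4, mec-17, ifc-2, gst-4, flp-2, oac-32 and act-5) and 8 gained one (unc-42, flp-1, lgc-26, rpl-38, rpl-35, hsp-4, jun-1 and unc-54), while 5 uncalled genes changed sign. No paired analysis was possible because the table has no values per library. For the same reason other size factors, DESeq2, voom, pseudocounts, other filters, camera, fry, leaving out libraries and other splits of the libraries were not run. Depth per library is unknown, and the 943 genes at few RIS reads mark where it limits the fold changes.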

Other observations

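Tests of the heat shock genes, of the degrees of freedom, of the read positions and of the tissue medians were chosen after the result was seen, and those of muscle markers, neighbours and the X chromosome before theirs was. Some gene families held more calls of a given direction than other genes. Of 67 families with at least 15 genes, tested in each direction by Fisher's exact test (134 tests), 17 tests passed a Benjamini-Hochberg threshold of 0.05. Among the 17 were tests of families that the fixed lists already cover in whole or in part, such as col, his, npr and hsp. Falls were concentrated in C-type lectins (clec, 65 of 98 genes, adjusted p = 7.42e-15), UDP-glucuronosyltransferases (ugt, 41 of 59, adjusted p = 2.21e-10) and cytochromes P450 (cyp, 40 of 64, adjusted p = 3.39e-08), families of defence and detoxification. The O-acyltransferase genes (oac, 15 of 18), astacin proteases (nas, 16 of 24), pals genes (12 of 17), math genes (13 of 19) and F-box genes (fbxa, 46 of 92) were lower too, and of these 8 families only cyp (3) and fbxa (1) had higher genes. Each of the 8 families had members at few RIS reads, many of them in fbxa and pals, and the tests were not matched on expression. Rises were concentrated in globins, oxygen-binding proteins (glb, 9 of 26, adjusted p = 0.00533), with 2 of 26 lower, led by glb-7 (6.68) and glb-23 (6.41) in the authors' deposited table. Of 17 arrestin-domain genes (arrd) 6 were higher (adjusted p = 0.0337), with arrd-26 (7.07) and arrd-17 (6.32) in the authors' deposited table, and 4 were lower, with a family median of 0.61. The families named for mutant phenotypes share a name and not a function and went both ways, with 32 higher and 16 lower of 92 unc genes, 8 and 4 of 20 egl genes and 8 and 7 of 24 daf genes.

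Of 14 genes on mitochondrial DNA 6 were higher and 0 lower, with a median log2 fold change of 1.40. The cytochrome oxidase genes ctc-1 (2.76) and ctc-3 (2.45) and the cytochrome b gene ctb-1 (2.05) rose in the authors' deposited table, with adjusted p from 0.00595 to 0.0237. The share of genes higher in RIS was 13.2% on the X chromosome and 9.21% on autosomes (odds ratio 1.5, Fisher's exact test, p = 3.51e-07), where genes are not independent replicates. The X chromosome also had 30.7% of its genes lower, against 26.4% of all genes, and a median log2 fold change of −1.11. Chromosome V had the highest share of genes lower in RIS, 35.2%. The hypothesis that close same-strand neighbours rise together, prompted by F46C5.4 and F46C5.7, was not decided. Of neighbours within 500 bases of a higher gene, 58 of 281 on the same strand and 64 of 406 on the opposite strand were higher (20.6% against 15.8%, Fisher's exact test, p = 0.105). A pair with both genes higher was counted from each side, so the entries are not independent and the p-value is approximate. Overlapping genes, which can share reads, were included. Both shares lie above the 9.84% of all genes, a difference that was not tested, so the missing contrast between strands does not exclude that neighbours rise together.

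The rise of 8 heat shock genes stands beside that of the RIS markers. Reads shared between near-identical copies could spread the rise of some copies to others, and the lowest log2 fold change of 7.09 does not decide this, because the 8 were taken for being higher. Stress from dissociation and sorting may account for the rise, whose median was 7.94. Use of these genes by RIS in the animal would also raise them, without setting a size such as 7.94. Handling stress and use in the animal cannot be told apart, because every RIS library was dissociated and no reference library was. An effect of strain cannot be told apart from either, because strain differed with the group as well.

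The 170 genes with 1 degree of freedom fewer were all lower in RIS and lay on a line of their own at the bottom of the plot of fold change against expression. With 3 libraries in each group each such gene would lose 2 degrees of freedom, and 0 of the 170 did, nor did any (0) with the replicate number as a block. With 2 RIS libraries in the fit the loss is 1, as seen for 170 of 170, so a candidate explanation is that the fold changes rest on 2 of the 3 labelled RIS libraries. For the 467 genes at the lowest positions above that line, a fitted model with 2 libraries of unequal size left 14.2% off its positions, and an added library of another size raised the log-likelihood by only 0.307. A loss of 1 also arises with 3 RIS and 2 reference libraries and the replicate number as a block (170 of 170) or with an added covariate that splits only the RIS libraries (6 of 30 possible 2-level covariates), and these, like an added library equal in size to another or far smaller than the others, stay open.

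Markers of 4 other tissues (pharynx, hypodermis, intestine and body wall muscle) were lower in RIS to different degrees, with list medians from −4.29 in the pharynx to −1.61 in body wall muscle, while the medians of glia (−0.67), germline (0.84) and coelomocytes (1.89) lay higher. RNA of the whole animal carried over in a fixed share, as the only source, would lower all tissues alike, and the ranges of 2.68 between the 4 medians and 6.18 between all 7 exceeded those under permutation of the genes (100000 permutations, p = 0.00354 and 0.000840). Genes of a tissue are not independent replicates, so these p-values are approximate. Muscle cells sorted along, as the only source and without gene-specific bias, would give their abundant transcripts a common fold change. The 12 muscle markers at or above 100 CPM ranged from −2.99 to 0.98 around a common −1.08 (heterogeneity chi-square on approximate errors, p = 1.12e-08), with pat-10 (−0.39, 8019 CPM) and unc-15 (−2.99, 3232 CPM) in the authors' deposited table far apart. Expression of some of these genes in RIS itself was not tested and stays open, alone or on top of either source. Handling and strain differed with the group, so a gene-specific bias could also spread the folds. The chi-square therefore cannot exclude sorted muscle with such a bias.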
